A study of Mus musculus with 16 samples.

How the data were processed

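RNA of mouse mammary epithelium was labelled with biotin and hybridised to Affymetrix arrays, 1 sample per array, after 17 cycles of amplification per the labels' protocols. The deposited table holds log2 levels for each array, made by the authors with RMA (background correction, quantile normalization and summary per probe set) and limma 3.32.10, per the submitters' processing notes; that the scale is log2 was read from the values, which lay between 3.76 and 13.8. The raw scans were not used here, and the order of the authors' steps is not given in the sources used here. RMA makes the overall distribution of the arrays alike, so shifts of all genes at once cannot be seen.

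Arrays were grouped by the cell type in the labels, 8 luminal and 8 basal, and numbered within a group in accession order. These numbers only name arrays and pair nothing. Of the 22269 probe sets, 19572 carry 1 gene symbol in the platform annotation, 0 carry several and 2697 none, among them 63 spike-in controls. All 19572 were matched by Entrez ID to a mouse RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols. Where a gene had several probe sets (55 genes), the one with the highest mean was used, over the 16 arrays for the planned comparison and over the 8 luminal arrays for the luminal description, leaving 19505 genes. Level was called above background where it exceeded 7.32, the 95th percentile of 1410 olfactory and vomeronasal receptor genes on the luminal arrays. Where the lowest array of a gene lay below that level and the highest above it, its fold is given as at least the highest over that level. None of the 120 pairs of arrays held identical values.

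The planned comparison was a limma fit with cell type as the term and no covariate, using limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment. On simulated values for 19505 genes it recovered 77% of genes changed by 0.5 and 95% of genes changed by 1 on the log2 scale, with 8 false calls. Row names were checked too. Values of the basal arrays did not go with the names of their rows, as the report shows. The correlation of neighbouring rows was 0.292 in luminal and 0.00676 in basal means. The names were put in 7 orders, as in the table, reversed, and sorted by symbol, Entrez ID, accession, probe set number and probe set name read backwards. Each order was tried at all shifts, and the highest correlation was 0.0309, against 0.0336 for the highest of 100 random orders. The order of the basal rows was therefore not recovered, and no row was matched by its value. The planned gene lists test (camera with a preset correlation of 0.01) and the planned comparison of Ehmt2 were not run. The rule for named genes fixed before the data were examined takes genes called between the cell types and was not used.

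The description of luminal genes was chosen after the data were seen. Its rule names the 20 genes with the largest SD between luminal arrays, leaving out predicted genes, up to 4 members of each list with the largest SD, and Ehmt2 and Ehmt1; further list members were named as examples of steady or low genes after their values were seen. The 27 gene lists themselves were fixed before the data were examined, and 486 of their 528 genes were measured. For each list with at least 5 measured members (26 lists), the median SD and the mean correlation between members were set against 10000 random lists matched on mean level in 20 bins, one-sided towards higher values, with Benjamini-Hochberg adjustment over the lists. In a simulation over 19505 genes, 10 of 10 lists with a shared factor were recovered by the correlation, and 0 of the lists without one were called. Simulated genes varied independently apart from that factor, which was as large as the noise. Real genes vary together, so the simulation gives neither the rate of false calls nor the power for weaker correlations. Erythrocyte markers had 3 measured members and no test.

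A test of single genes was tried first and set aside. It compared each gene's variance between luminal arrays with the prior distribution of variances that limma fits, and it called 1 of 19505 genes, Klk6, with 1384 at an unadjusted p under 0.05. On simulated values it recovered 0% of genes with 3 times and 0% of genes with 6 times the usual SD. It therefore had no power at these sizes. Larger SDs were not simulated and false calls were not counted, so the call of Klk6 is not judged by it. No gene's spread is called from this test.

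Means of lists were related to that of the interferon list across the 8 luminal arrays by exact two-sided permutation of Pearson's and Spearman's coefficients, 28 relations in all, with shared genes removed. Coefficients are not given for lists whose arrays fell into separate clusters. Spread between arrays was tested by an exact two-sided permutation test over 12870 splits. It permuted each array's finished value without recomputing it, so its p-values are approximate. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered normalization, filters on dim probe sets, the choice of probe set, the variance prior, weights, the test, covariates and leaving out each array.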

Results

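Gene expression was measured on 16 microarrays of mouse mammary epithelium, 8 labelled luminal and 8 labelled basal. Luminal cells line the ducts and alveoli and make milk, and basal cells surround them and contract. The study addressed the loss of G9a, the histone H3K9 methyltransferase encoded by Ehmt2, in the developing gland, and the silencing of endogenous retroviruses. The labels used here give the cell type of each array and no genotype, so no comparison by genotype was made and no array was assigned to one. Each array held log2 levels for 22269 probe sets, with array medians between 7.98 and 8.09. Nothing in the labels says that the arrays come from separate animals. Tests across arrays therefore measure the spread between these samples, which may be technical. The p-values of single lists set a list against random genes on the same arrays and do not measure that spread. Genes of the random lists were drawn singly, so the p-values for SD can be too small where members vary together. The number of arrays limits the precision of every value.

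The first comparison asked which genes differ between luminal and basal cells. The ribosomal protein genes, which encode the parts of the ribosome, had a luminal median of 12.70 over 60 rows, and their rows had a basal median of 7.76. For random rows the 95% range of that median was 7.29 to 8.85 in luminal arrays and 7.31 to 8.83 in basal arrays. A set of 7 housekeeping genes, chosen after the data were seen, had luminal means between 12.78 for Gapdh and 13.41 for Eef1a1. The basal means of their rows were 5.89 for B2m, 6.85 for Eef1a1, 9.80 for Actb and for Fth1, 10.10 for Rpl4, 10.39 for Gapdh and 11.77 for Tpt1. Their basal median of 9.80 lay inside the 95% range of random rows, 6.02 to 10.21, while 5 of the 7 lay above the upper quartile of the basal levels, 9.68, as many as in a share of 0.012 of random sets.

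Receptor genes of the nose showed the opposite. The olfactory and vomeronasal receptor genes, which epithelia outside the nose rarely transcribe, had a luminal median of 5.40 over 1412 rows and a basal median of 7.92, with 7.89 to 8.20 for random rows. Over all rows the luminal and basal means had a Pearson correlation of 0.0133 and a Spearman correlation of 0.0154, across probe sets, which are not independent replicates. Sorted by size, the same luminal and basal means correlated at 0.99994. Quantile normalization makes that value high whatever the order of the rows. Pairs of luminal arrays correlated at 0.981 to 0.993 and pairs of basal arrays at 0.974 to 0.993, and each of the 64 luminal and basal pairs correlated at 0.00905 to 0.0180.

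**Figure D1:**
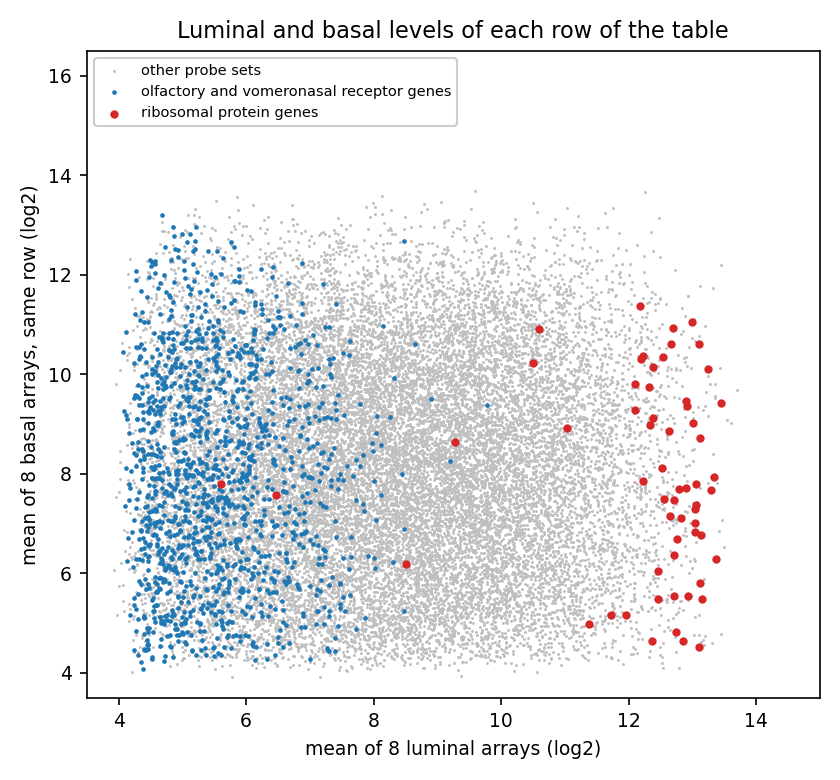
Each point is 1 row of the table, with its mean over the 8 luminal arrays on the horizontal axis and its mean over the 8 basal arrays on the vertical axis, both in log2. Ribosomal protein genes lie mostly at the right, with a luminal median of 12.70, while their basal values spread around a median of 7.76.

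With limma (Benjamini-Hochberg adjustment), 18344 of 19505 genes passed an adjusted p of 0.05 between the cell types. Of these, 9251 were higher and 9093 lower in luminal arrays, and 14418 also differed by at least 1 on the log2 scale. When the rows of the basal arrays were shuffled at random 20 times, the same fit called between 93.6% and 94.3% of genes, against 94.0% for the table itself. The count is therefore not a count of genes that differ between luminal and basal cells. No gene name was attached to a basal value, and no gene was compared between the cell types. The planned comparisons of Ehmt2 and of the gene lists between luminal and basal cells were left out for the same reason.

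Named genes were described within the luminal arrays. The 20 measured pan-luminal markers were above background in every luminal array, and the mean of the list moved by 0.05 log2 from the lowest to the highest array, over members that did not vary together (mean correlation -0.00811). The keratins of the lining layer, Krt8 and Krt18, read 13.02 ± 0.11 and 13.04 ± 0.13 (SD, n = 8). Epcam, an epithelial adhesion molecule, read 12.62 ± 0.12, and Cdh1, which encodes E-cadherin, read 13.07 ± 0.05. The most variable members were Muc1, a mucin of the apical surface, which spanned 1.91-fold, and Cd24a, which spanned 1.64-fold. The median SD of this list was 0.13 log2, against 0.11 for random lists of like level (adjusted p = 0.166 over 26 lists). Pgr, the progesterone receptor, read 12.38 ± 0.12.

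Ehmt2, the gene the study deleted, read 11.28, 11.29, 11.28, 11.41, 11.26, 11.32, 11.38 and 11.13 in luminal replicates 1 to 8. Its mean was 11.29 ± 0.08 (SD, n = 8), and the SD was 0.05 without replicate 8. Its partner Ehmt1, which encodes the related methyltransferase GLP, read 10.78 ± 0.09, between 10.62 and 10.88. The probe set may lie outside the deleted part of Ehmt2, so these levels check no genotype. The list of H3K9 methylation and retroelement silencing factors had a median SD of 0.14 against 0.15 for random lists (adjusted p = 0.663). In that list 30 of 31 measured members were above background in every luminal array, among them Setdb1 at 10.04 ± 0.10 and Trim28 at 10.61 ± 0.18.

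Genes of nucleic acid sensing and the interferon response differed most between luminal arrays among the lists, and they varied together. Of the 32 measured members, 25 differed by at least 1 log2 between their lowest and highest array. Irf7, the transcription factor that drives interferon production, lay between 7.46 and 11.13, a 12.7-fold range. The chemokine gene Cxcl10 spanned 9.22-fold. Ifit3 and Ifit2, interferon-induced antiviral proteins, were below background in 1 and 3 arrays and so spanned at least 8.42-fold and 3.08-fold, counted from the background level. Mavs and Irf3, which relay RNA and DNA sensing, spanned 1.30-fold and 1.21-fold.

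The mean of the interferon list was lowest in replicate 8 at -0.91 and highest in replicate 3 at 0.94, relative to each gene's mean, a 3.60-fold range. The other arrays lay at -0.73, -0.11, 0.66, -0.42, 0.44 and 0.14 for replicates 1, 2, 4, 5, 6 and 7. Pairs of its members correlated at 0.745 on average across the 8 arrays, against 0.0116 for random lists of like level (p = 1e-04, the smallest that 10000 random lists can give; adjusted p = 6.5e-04 over 26 lists). The median SD of its members was 0.79 against 0.15 (adjusted p = 4.33e-04).

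The mean of the genes that restrict retroelements varied with that of the interferon list, and 5 of the 15 measured members differed by at least 1 log2 between arrays. Trim30d and Trim30a, of a family of interferon-inducible TRIM proteins, spanned at least 15.5-fold and 11.5-fold. Bst2, or tetherin, spanned 3.40-fold, and Samhd1, which depletes nucleotides for reverse transcription, 2.39-fold. Other members spanned little, such as Apobec3 at 1.31-fold, Rnaseh2c at 1.30-fold and Marchf8 at 1.19-fold. The list shares Bst2 with the interferon list. The interferon-inducible Trim30d and Trim30a had its largest SDs, 1.32 and 1.21, and stayed in when Bst2 was removed. A high correlation was therefore likely in advance, and it does not tie retroelement restriction as such to the interferon response. Without Bst2, its mean correlated with that of the interferon list across the 8 luminal arrays at Pearson r = 0.955 (exact permutation p = 6.45e-04, adjusted p = 0.0181) and Spearman rho = 0.952 (exact permutation p = 0.00114, adjusted p = 0.0319). Without the 2 arrays farthest from the median, r was 0.956. The adjusted p was 0.119 without replicate 3, 0.0556 without replicate 1 or 4, and at the 0.05 threshold without replicate 6 or 7.

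This was 1 of 28 relations with the interferon list, and with all 8 arrays it alone passed an adjusted p of 0.05. The fibroblast marker list moved with the interferon list at r = 0.876 (exact permutation p = 0.00575, adjusted p = 0.0806) and rho = 0.905 (exact permutation p = 0.00456, adjusted p = 0.0639), with r = 0.789 without the 2 farthest arrays. Without replicate 2 it passed, at r = 0.929 (adjusted p = 0.0306). For basal stem cell associated genes, r was 0.855 (exact permutation p = 0.00987, adjusted p = 0.0921) and rho 0.833 (exact permutation p = 0.0154, adjusted p = 0.144). For Ehmt2, r was 0.664 (exact permutation p = 0.0636, adjusted p = 0.248) and rho 0.571 (exact permutation p = 0.151, adjusted p = 0.399). By Pearson's coefficient the strongest negative relation was that of contractile genes, at r = -0.771 (exact permutation p = 0.0326, adjusted p = 0.209) and -0.923 without the 2 farthest arrays, with rho = -0.690 (exact permutation p = 0.0694, adjusted p = 0.278). By Spearman's it was that of pan-luminal markers. For pan-luminal markers, r was -0.700 (exact permutation p = 0.0561, adjusted p = 0.248) and rho -0.762 (exact permutation p = 0.0368, adjusted p = 0.257). For leukocyte markers, r was 0.577 (exact permutation p = 0.133, adjusted p = 0.371) and rho 0.548 (exact permutation p = 0.171, adjusted p = 0.399).

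**Figure D2:**
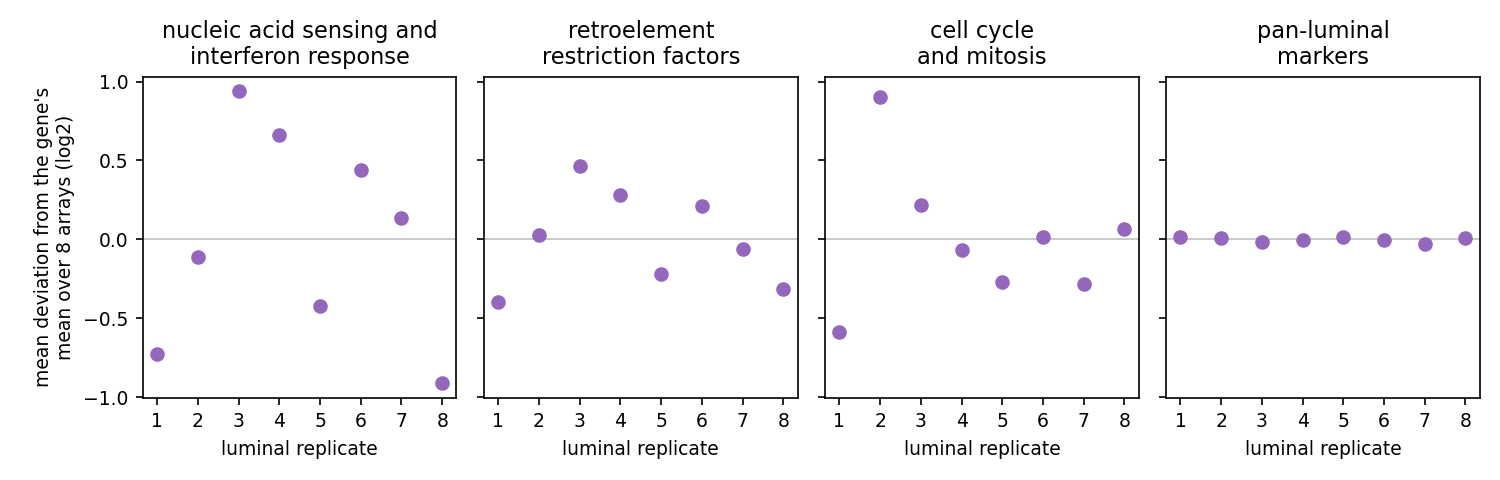
Each point is the mean of 1 gene list on 1 luminal array, as the difference in log2 from each gene's mean over the 8 arrays, with the replicate on the horizontal axis. The interferon list spans -0.91 to 0.94 and the cell cycle list -0.58 to 0.90, while pan-luminal markers move by 0.05 in all.

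Genes of the cell cycle and mitosis also varied together. Of 28 measured members, 21 differed by at least 1 log2 between arrays. The kinase gene Cdk1, which starts mitosis, spanned 7.26-fold, and Cdc20, an activator of the anaphase-promoting complex, spanned 5.10-fold. Cenpe, a kinetochore motor, was above background in 4 arrays and reached 9.05, and Bub1, a checkpoint kinase, was above it in 1 array and reached 8.50. The list mean was highest in replicate 2 at 0.90 and lowest in replicate 1 at -0.58, a 2.80-fold range. The next highest was replicate 3 at 0.22, so that range rests in part on replicate 2. Its members correlated at 0.719 on average, against 0.00273 for random lists (adjusted p = 6.5e-04). Without replicate 2 the mean correlation was 0.448 (adjusted p = 0.00087).

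Markers of the luminal subsets varied as well, more weakly. In the hormone-sensing list, members correlated at 0.320 on average (adjusted p = 6.5e-04), and Tph1, the enzyme that starts serotonin synthesis, spanned 4.79-fold and Cited1, a transcriptional co-regulator, 3.12-fold. In the luminal progenitor and alveolar list the mean correlation was 0.216 (adjusted p = 0.0123), with Lbp spanning 5.31-fold, Hey1 3.92-fold and Elf5, a regulator of alveolar fate, 2.36-fold. That adjusted p was 0.0695 without replicate 3 and 0.0650 without replicate 7. Milk protein and lactation genes had a median SD of 0.42 against 0.15 for random lists (adjusted p = 4.33e-04), with Csn1s1, an alpha casein, spanning at least 12.1-fold and Wap, whey acidic protein, 3.94-fold. Their mean correlation was 0.0736 (adjusted p = 0.212, and 0.0342 with genes above the median level, where 10 of the 14 members were tested). Csn2, beta casein, was below background in every luminal array, and Csn3, kappa casein, read 12.95 ± 0.13 (SD, n = 8).

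Among markers of basal cells on the luminal arrays, 13 of 26 measured genes were above background in every array. Their median SD was 0.31 against 0.16 for random lists (adjusted p = 4.33e-04), and their mean correlation was 0.0130 (adjusted p = 0.570). Krt5, a basal keratin, spanned at least 5.72-fold and Acta2, smooth muscle actin, 3.91-fold. Contractile genes correlated at 0.185 on average (adjusted p = 0.0026), with Cald1, caldesmon, spanning 4.13-fold. Immediate early and dissociation stress genes correlated at 0.170 (adjusted p = 0.0039), and at 0.0512 without replicate 2 (adjusted p = 0.356). Hsph1 spanned 2.47-fold.

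Fibroblast markers had a median SD of 0.27 against 0.17 (adjusted p = 0.0026) and a mean correlation of 0.213 (adjusted p = 0.00409), which was 0.123 without replicate 8 (adjusted p = 0.0614). Of the 15 measured fibroblast markers, 6 differed by at least 1 log2 between arrays. Dcn, the matrix proteoglycan decorin, had the largest SD, spanned at least 15.8-fold and reached 11.31. The collagen gene Col1a1 read 9.42 and spanned only 1.11-fold, and Col1a2 spanned at least 1.19-fold. Col3a1 and Lum were below background in every luminal array. Of the leukocyte markers, 13 of 19 were below background in every luminal array, and their median SD was 0.16 against 0.17 (adjusted p = 0.653). Endothelial markers had a median SD of 0.31 against 0.17 (adjusted p = 9.75e-04), and the adjusted p was 0.337 without replicate 3.

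Over all genes, 544 of 19505 had an SD above 0.5 log2 between luminal arrays and 72 an SD above 1. Klk6, a secreted serine protease of the kallikrein family, had the largest, 2.49 log2, with levels from 7.64 to 13.03. Selp and Il6, which encode P-selectin and interleukin 6, followed with 2.13 and 2.09, though only 1 array was above background for Selp and 4 were for Il6, so their SDs rest partly on levels at background. Without replicate 3 the SD of Selp was 0.19 and that of Sele, E-selectin, also above background in 1 array, was 0.16. Of the other genes in the top 20, Ifi211, Tgtp2, Ifit1bl1 and Ifit3b belong to interferon-inducible families and were above background in 2, 4, 5 and 6 arrays. In all, 15 of the 20 genes were not above background in every array. Klk14 and Klk8 are further kallikreins. These SDs describe the arrays and none is called. A test of single genes was tried, called Klk6 alone and was set aside. It recovered 0% of genes simulated with 3 or 6 times the usual SD, and larger SDs were not simulated.

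**Figure D3:**
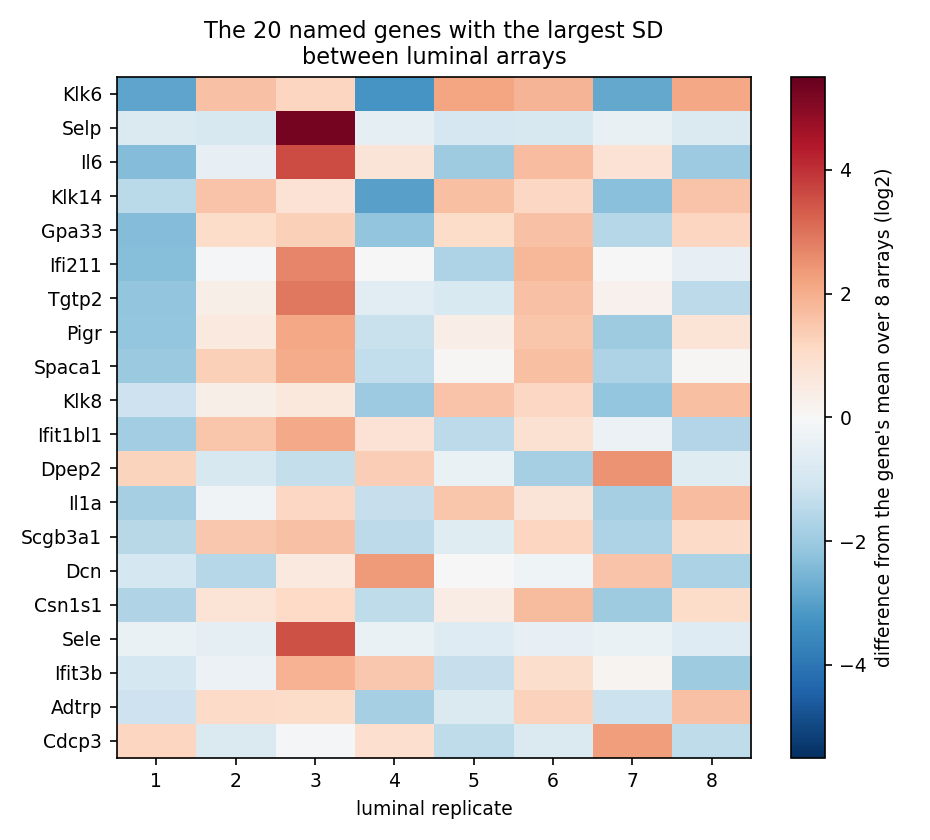
Colours show the level of each of the 20 genes with the largest SD on each luminal array, as the difference in log2 from that gene's mean over the 8 arrays. Selp and Sele stand out in replicate 3, and Klk6 ranges from 7.64 to 13.03 between arrays.

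The spread between arrays was compared between the cell types, which needs no gene names. On average, these basal arrays differed more from one another than the luminal arrays did. The spread holds any unlabelled difference of genotype, animal or processing, so it cannot be read as a trait of the cell types. An array's root mean square difference from the mean of the other arrays was 0.278 ± 0.034 log2 in basal arrays and 0.243 ± 0.021 in luminal arrays (SD, n = 8 each; two-sided exact permutation p = 0.0232 over 12870 splits). The p-value is only approximate: an array's value depends on the other arrays of its group, and values were permuted without being recomputed. Basal replicate 2 had the highest value at 0.338 and luminal replicate 5 the lowest at 0.208. The difference lost the 0.05 threshold when luminal replicate 4, 5, 6 or 7 or basal replicate 2 or 5 was left out, with p up to 0.0793. Over all probe sets, 922 had an SD above 0.5 between basal arrays and 609 between luminal arrays.

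**Figure D4:**
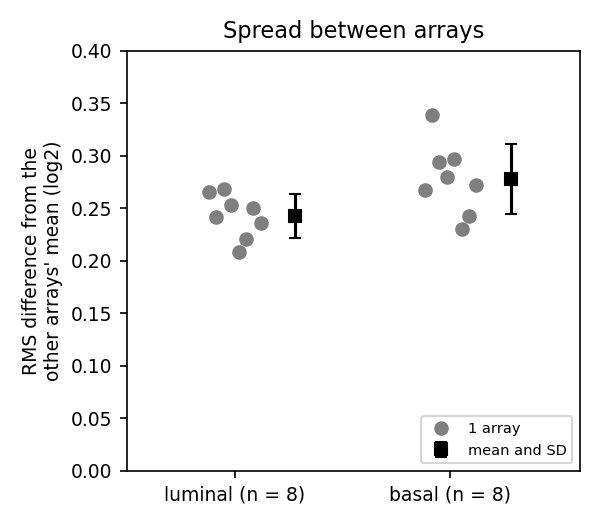
Grey points are single arrays and black squares with bars the mean and SD of 8 arrays. The vertical axis is the root mean square difference in log2 of an array from the mean of the other arrays of its cell type, 0.243 on average in luminal and 0.278 in basal arrays.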

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

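All tests of explanations in this part were chosen after the results were seen. An array was picked out where the gap to its nearest neighbour, divided by the range of the 8 arrays, passed Dixon's 95% critical value for 8 values. Of 152 genes, lists and array measures examined, 8 passed. Chance alone flags about 1 in 20 of unselected values. Apart from Ehmt2 and Ehmt1, the genes were picked for a large SD on these same arrays, which a single outlying array raises. That rate therefore does not hold for them.

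Levels of a row were unrelated between luminal and basal arrays, where 18344 of 19505 genes were called. Ribosomal protein genes argue against expression as the cause: 54 of 60 rows lay in the top 10% of the luminal levels and 4 in the top 10% of the basal levels, where chance gives 6, although 5 of 7 housekeeping rows lay above the upper quartile of the basal levels (share of random sets 0.012). A difference of scale or normalization keeps the order of rows and is argued against by the rank correlation of 0.0154. A candidate explanation is that the basal rows stand in another order than the names: the ribosomal protein rows had a basal median of 7.76, inside the range of random rows. Which step could have changed the order stays open.

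For the count of 18344 genes alone, 1 of 100 splits of the 16 arrays, the real one, called as many, and the highest other split called 0 with limma (at most 11186 at an unadjusted p under 0.05). Arrays correlate at 0.974 or more within a cell type and at no more than 0.0180 between the types. Mixed splits therefore had to call few genes after adjustment, and this says nothing about why the rows are unrelated.

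For interferon response genes, which varied together between luminal arrays, leukocytes in the luminal sort are argued against as the main source. Lyz2, Tyrobp and Cd52, abundant transcripts of leukocytes, stayed below background in every array, while Irf7 reached 11.13. Ptprc, Coro1a, Laptm5, H2-Aa and H2-Ab1 were above background in every array, with SDs from 0.07 for Coro1a to 0.19 for Ptprc. The 5 leukocyte markers with a mean above background moved by a median of 0.0383 log2 per log2 of the interferon list (95% interval -0.0498 to 0.0444), and all 19, of which 13 were below background in every array, by 0.0444. For fibroblasts the median was 0.128 over 15 markers, with an interval of 0.0309 to 0.559, and over the 8 markers with a mean above background it was 0.0409 (0.0186 to 0.128). That is a smaller slope than over all 15, though 7 of these 8 markers moved upwards with the interferon list. All these intervals resample markers over the same 8 arrays, so they leave out the spread between arrays. Fibroblasts may contribute and cannot be told apart. Genotype, the difference the study made, is in no label and stays open, as untested.

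Selp and Sele stood apart in luminal replicate 3. Selp read 11.68 there and 5.69 ± 0.19 in the other 7 arrays (ratio of gap to range 0.920), Sele read 9.01 against 5.01 ± 0.16 (0.911), and the endothelial gene Emcn, below background in every array, read 6.80 against 5.56 ± 0.20 (0.636). Endothelial cells in that sample may contribute: 5 of the 14 endothelial markers, Pecam1, Cdh5, Kdr, Emcn and Erg, lay at least 0.5 log2 above the mean of the other arrays, yet Kdr and Emcn were above background in no array, and Pecam1, Cdh5 and Erg reached only 8.07, 7.33 and 7.51 there. The median of the 14 was 0.11 above the other arrays in replicate 3 and 0.14 above in replicate 7, where Cdh5 read 7.82 but Selp 6.02. These differences are taken largely against levels at background, so the markers do not decide whether endothelial cells contributed. No other biological explanation was tested.

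Other single arrays stood apart as follows. Phlda3, a p53 target, read 6.90 in replicate 3 against 7.80 ± 0.12 (0.679). Fosb, an immediate early gene, read 10.83 in replicate 2 against 11.77 ± 0.12 (0.700). Fabp4, a fatty acid carrier of adipocytes and endothelium, read 7.88 in replicate 1 against 10.04 ± 0.50 (0.575). Eda2r, a TNF receptor family member, was highest in replicate 1, above the other arrays at 7.42 to 8.14 (0.541). The mean of 3 erythrocyte markers was -0.15 in replicate 8 against 0.02 ± 0.03 (0.530).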

How the results depend on the processing

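The alternatives for genes and lists of the luminal arrays were chosen after seeing the data; those for the comparison of cell types and for the spread between arrays were planned, except the use of every probe set and the filter on each cell type's own levels for the spread. The count of 18344 genes between luminal and basal was 9163 with genes above the median level and 4549 with genes above the 75th percentile, where fewer genes were tested (9752 and 4876), and 13408 to 20937 under the other 10 settings; leaving out an array gave 18273 to 18339. None of these counts is a count of genes that differ. The higher spread of basal arrays kept its direction and p under 0.05 in the 5 other settings (p from 0.00109 to 0.0250), and leaving out an array gave differences of 0.0266 to 0.0459 log2 with p from 0.00311 to 0.0793. The 544 genes with an SD above 0.5 became 308 with genes above the median level, again among fewer genes, and 520 to 594 without 1 array. Of the lists, 8 varied together, 8 under each of 4 other settings and 7 to 8 without 1 array. With genes above the median level these were not all the same lists: fibroblast markers had too few members to test, and milk protein and lactation genes passed. The 15 lists that varied more than genes of like level became 10 with genes above the median level, where fibroblast, endothelial and Schwann cell markers had too few members to test, 13 to 15 under the other settings and 13 to 18 without 1 array. The interferon list kept a mean correlation of 0.718 to 0.765 and the cell cycle list 0.448 to 0.779 under all 12 settings. The interferon and restriction factor lists correlated at 0.934 to 0.972 without 1 array, with adjusted p up to 0.119, reached without replicate 3. The cause was not tested. Alternatives planned for the gene lists test and for Ehmt2 between luminal and basal cells were not run, because basal rows carry no usable names. No paired analysis was possible because the labels give no pairing of arrays. Dim genes limit the lists of other cell types: 13 of 19 leukocyte markers lay below background.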

Other observations

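The kallikreins are secreted serine proteases, and 3 of them were among the 20 genes with the largest SD between luminal arrays; this and what follows was chosen after the values were seen. Of 25 measured kallikrein genes, 12 were above background in every luminal array and 9 had an SD above 0.5 log2 (36%), against 544 of 19505 genes (2.79%). This excess was not tested. Their SDs were 2.49 for Klk6, 1.93 for Klk14, 1.55 for Klk8, 1.21 for Klk13, 1.13 for Klk11, 1.10 for Klk12, 0.73 for Klk10, 0.71 for Klk7 and 0.65 for Klk9.

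Levels of several genes fell into separate clusters of luminal arrays, which the labels do not name. Klk6 read 7.98, 12.47, 12.07, 7.64, 13.03, 12.73, 8.06 and 13.01 in replicates 1 to 8. Klk14 read 8.92, 11.99, 11.21, 7.42, 12.07, 11.55, 8.09 and 11.96. Gpa33, a cell surface antigen of gut epithelium, read 7.08, 10.47, 10.76, 7.28, 10.47, 11.07, 7.89 and 10.62. Csn1s1, an alpha casein, read 7.53, 9.92, 10.26, 7.79, 9.59, 10.92, 7.24 and 10.19. The widest gap between neighbouring values was 4.01 log2 for Klk6, 2.29 for Klk14, 2.58 for Gpa33 and 1.81 for Csn1s1, with replicates 1, 4 and 7 below it in each. Of the 20 genes with the largest SD, 8 had replicates 1, 4 and 7 below their widest gap, also Pigr, Spaca1, Klk8 and Il1a. Of these 8 genes, Klk6, Klk14 and Klk8 were above background in every array, Csn1s1 in 7, Gpa33 in 6, and Pigr, Spaca1 and Il1a in 5. In Dpep2, above background in 3 arrays, replicates 2, 3, 5, 6 and 8 lay below the widest gap. The mean of the milk protein and lactation list, whose members did not pass the test for varying together (mean correlation 0.0736, adjusted p = 0.212), was -0.33, 0.16, 0.23, -0.34, 0.18, 0.32, -0.38 and 0.16. That of the luminal progenitor and alveolar list was -0.14, 0.09, 0.32, -0.12, -0.06, 0.19, -0.23 and -0.04, and that of the hormone-sensing list was 0.17, -0.04, -0.30, 0.18, 0.07, -0.17, 0.08 and 0.02. The set of replicates 1, 4 and 7 was read from these same values, among genes picked for a large SD. It was not tested, and no groups of arrays were compared.

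Rhox5, an X-linked homeobox gene of the germline list, was above background in every luminal array and spanned 4.44-fold, from 8.27 to 10.42. Sycp3, a protein of the meiotic chromosome axis, spanned 2.58-fold. The germline list as a whole had a median SD of 0.16, the same as random lists to 2 decimals (adjusted p = 0.484), and 12 of its 20 measured members were below background in every array.

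Further lists on the luminal arrays gave the following median SDs. The first 10 lists varied more than genes of like level. The EGF and FGF ligands and receptors had 0.23 (adjusted p = 0.00433), with Epgn, epigen, spanning 3.53-fold. Schwann cell markers had 0.28 (adjusted p = 0.00433), basement membrane genes 0.19 (adjusted p = 0.0384), and tight junction genes 0.16 (adjusted p = 0.0456). The Schwann cell markers did not pass the test for varying together (mean correlation -0.0567, adjusted p = 0.864). Of their 8 measured members, 3 were below background in every array, and Sox10 and Erbb3 also stand in lists of luminal markers. Basement membrane genes lost the threshold after quantile normalization, with genes above the median level, and without replicate 3 or 5 (adjusted p up to 0.0815). Tight junction genes lost it after quantile normalization or centring on medians, and without replicate 1, 2, 4 or 5 (adjusted p up to 0.185). Retroelement restriction factors had 0.28 (adjusted p = 7.43e-04), hormone-sensing markers 0.26 (adjusted p = 0.00173), luminal progenitor markers 0.27, cell cycle genes 0.47 and immediate early genes 0.24 (adjusted p = 4.33e-04 for each), and contractile genes 0.21 (adjusted p = 0.0094, and 0.0789 with genes above the median level). Values that missed the threshold were 0.21 for basal stem cell associated genes (adjusted p = 0.0624), 0.18 for the Notch pathway (adjusted p = 0.166), 0.19 for the Wnt pathway (adjusted p = 0.0827), 0.19 for regulators of epithelial-mesenchymal transition (adjusted p = 0.105), 0.19 for p53 and arrest genes (adjusted p = 0.0904), 0.19 for pericyte markers (adjusted p = 0.281) and 0.19 for adipocyte markers (adjusted p = 0.166). Of these, basal stem cell associated genes passed without replicate 2, 6 or 8 (lowest adjusted p = 0.0394), p53 and arrest genes without replicate 6 or 8 (0.0471) and the Wnt pathway without replicate 6 (0.0490).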
